A study of Mus musculus with 9 samples.

How the data were processed

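Nuclei from whole frozen livers of 9 mice were profiled with 10x Genomics 3' v3 chemistry, 1 library per mouse, in 3 groups of 3 given by the labels: healthy, CDE and TAA. Per the submitters' processing notes, the authors used bcl2fastq and Cell Ranger 3.0.2 with build mm10. The deposited matrices hold raw UMI counts for 28692 genes and all 6794880 barcodes of the chemistry in each library, with no cells chosen and no normalization. Whether introns were counted and which annotation release was used are not stated. Library totals ran from 21736711 to 85740692 UMIs, and counts per gene and class set the precision of each value through the edgeR dispersion fit. Counting intervals cover counting error only.

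Nuclei were called as Cell Ranger 3 does: barcodes above the 99th percentile of the top 3000 divided by 10, then barcodes of at least 500 UMIs tested against the profile of barcodes ranked 45001 to 90000 with 10000 simulated profiles at an adjusted p of 0.01. In TAA 1 that range held barcodes of at most 18 UMIs and both steps called 16358 barcodes, so it was moved to ranks 20001 to 30000, where the first step called 1255 and the test added none, unlike in the other libraries; calling as first written is an alternative chosen after seeing the data. Nuclei with under 500 UMIs, under 300 genes or at least 5% mitochondrial UMIs were left out, and Scrublet scores removed 0.8% per 1000 nuclei as doublets. Of 49158 called nuclei, 48462 passed the filters and 46193 were left after doublet removal.

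Clustering used scanpy 1.11.5 and leidenalg 0.10.2 on 3000 variable genes, 40 components and 20 neighbours at resolution 1, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Clusters were named by 11 marker lists (hepatocyte, cholangiocyte, endothelial, stellate and mesenchymal, macrophage and monocyte, T and NK, B and plasma, neutrophil, dendritic, mesothelial and erythroid) on profiles with the empty-droplet profile subtracted. The minimum naming score was lowered after the clusters were seen, from 0.45 to 0.35 and then to 0.25, with the lead over the next class kept at 0.15; this was done before any gene was tested and named 1 further cluster of 2797 nuclei as hepatocytes, with a hepatocyte score of 0.36 against 0.16 for the next class. Values without that cluster are an alternative chosen after seeing the data. Clusters that no class led, that doublets made up, that mitochondrial-encoded genes led or that had more markers of another class among their top genes were left unnamed (3316 nuclei) and not tested.

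Counts were summed per class and mouse where at least 20 nuclei were present. Genes were kept by filterByExpr, normalized by TMM and tested by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with all groups in 1 fit per class and Benjamini-Hochberg adjustment over the genes tested at 0.05. In classes other than hepatocytes, genes for which the empty-droplet profile, scaled as far as hepatocyte markers allow, could supply over 25% of the counts of a compared group were left out. Coordinates are from the GENCODE annotation of GRCm38 (mm10).

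The 22 hepatocyte gene lists were pericentral, periportal, hepatocyte identity, bile acid, xenobiotic phase I, NRF2 and glutathione, p53 targets, lipogenesis, cholesterol synthesis, fatty acid oxidation, lipid droplet, methionine with choline and one-carbon, injury and fetal, YAP targets, acute phase, unfolded protein and amino acid stress, cell cycle, circadian, male-biased, female-biased, mitochondrial-encoded and ribosomal protein. The 8 lists of other classes were sinusoidal identity, angiocrine and capillarization (endothelial), activation and quiescence (stellate), resident Kupffer and monocyte with lipid-associated (macrophage) and reactive (cholangiocyte). Lists were tested by camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation none of the 14 CDE, 15 TAA, 19 TAA against CDE and 9 other-class calls was kept. With the preset correlation, other splits of the same mice passed up to 12, 14 and 16 hepatocyte lists. A list call at the preset correlation alone therefore does not set the real groups apart. The lists, tests, comparisons and most alternatives were chosen before the data were examined, as was the rule for named genes: per direction, the 5 genes (3 outside hepatocytes) with the largest fold change among those past the threshold, of high expression (average log2 CPM of at least 5, or 6 outside hepatocytes) and with separate groups, and up to 4 members per list in order of p. Of the genes this rule took, 1 is not reported here. Gene models named only by number, mitochondrial-encoded genes and genes without counts in a group were not named by its first part.

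Detection shares, the zonation correlation and the injury share used nuclei of at least 1000 UMIs, thinned to 1000. Exact permutation tests, 2-sided, ran over the 280 splits of 9 mice into 3 groups of 3. Shares of classes were compared with the same test on logit shares. The relation between both exposures was set against 30 simulations in which unchanged groups shared the healthy libraries. All 9 libraries were redrawn in each, gene by gene, from the healthy means. Methods were tested on simulated changes: of genes changed 4-fold, between 32% and 48% were found in hepatocytes, and between 47% and 77% in other classes, and of genes changed 2-fold 0% to 2% and 1% to 14%. Alternatives covered normalization (RLE), the test (DESeq2 1.42.0), low-count filters, the replicate number as a block, thinning to the smallest total, UMI, mitochondrial and doublet limits, clustering at a doubled resolution, calling rules, free RNA and leaving out each mouse. List values with an estimated correlation and by fry for TAA against CDE depended on the linear algebra kernel, which was fixed to 1 kind, and another kind moved them slightly with no change of call. The labels do not say that replicate numbers pair mice, and the values did not pair them. Subtraction of the empty-droplet profile and scaling on the genes tested were also added after seeing the data. So were the counts of list members kept under them and of clusters by group outside hepatocytes.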

Results

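Single-nucleus RNA sequencing of whole frozen mouse liver was deposited as 9 libraries, 1 per mouse, with 10x Genomics 3' v3 chemistry. The mice were male C57BL/6J animals, 9 weeks old at harvest, in 3 groups of 3: healthy controls, mice given a choline-deficient diet with 0.15% ethionine in the water (CDE), and mice given thioacetamide, a hepatotoxin, at 300 mg/L in the water (TAA), each for 3 weeks. Nuclei were stained with propidium iodide and sorted before loading, and the submitters' values were raw UMI counts for every barcode of the chemistry, with no cells chosen. Libraries held 38079016, 38031710 and 37839177 UMIs in healthy mice 1 to 3, 34727408, 42403792 and 37189787 in CDE mice, and 21736711, 79287535 and 85740692 in TAA mice. After calling, filters and doublet removal, 17376 healthy, 16266 CDE and 12551 TAA nuclei remained, set beside 16222, 14507 and 10019 stated in the series text. Of these, 7979, 1919 and 5339 were hepatocyte nuclei. The fold change of each gene is given as log2 ± SE from the edgeR fit and normalised UMI counts (CPM) as mean ± SD, with n = 3 mice per group unless stated. Gene tests in macrophages lacked healthy 3 and those in cholangiocytes lacked healthy 1, which left 8 mice in each fit.

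The comparison of CDE with healthy mice asked which hepatocyte genes the diet changed, in a series whose stated aim is the cell states of the chronically injured, pre-malignant liver. Hepatocytes of CDE mice had a lower male-biased and a higher female-biased list, as 8 of 21 measured male-biased members fell, and 4 of 17 female-biased ones rose and 1 fell. Neither list call held with an estimated correlation (adjusted p = 0.220 and adjusted p = 0.220). Cyp2a4, a female-biased steroid hydroxylase (ENSMUSG00000074254, chromosome 7, 26307169 to 26315088, build GRCm38), rose by 8.71 ± 0.84 on the log2 scale, from 0.358 ± 0.62 to 220.3 ± 119.5 CPM (adjusted p = 0.00108), and Cyp2b9, a female-biased cytochrome P450, by 7.01 ± 0.53 (adjusted p = 4.81e-04). Healthy 1 and 2 had 0 CPM of Cyp2a4 and healthy 3 had 1.07, and without healthy 3 the log2 fold change was 13.92, so its size rests on that mouse. Cyp2a4, Cyp2b9, Serpina1e, Gsta1 and the Mup genes have near-identical paralogs, and how the reads divide within each family is uncertain. Serpina1e, of the alpha-antitrypsin family (ENSMUSG00000072849, chromosome 12, 103946931 to 103958975), changed by -9.23 ± 0.73, from 545 ± 240.1 to 0.969 ± 1.36 CPM (adjusted p = 4.81e-04), and free RNA could account for 89.9% of its remaining CDE counts. CDE 2 held 2.52 CPM of Serpina1e, and without it the CDE mean moved by over 1.5 times. Slco1a1, an organic anion and bile acid uptake transporter (ENSMUSG00000041698, chromosome 6, 141907282 to 141946962), changed by -5.22 ± 0.57 (adjusted p = 0.00166).

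In the list of male-biased genes, 8 of 21 measured members fell (16 adjusted over the list alone) and none rose, with a median log2 fold change of -2.48. The male-biased test by limma camera gave adjusted p = 5.19e-10, and adjusted p = 0.220 with an estimated correlation. Susd4 (-4.64 ± 0.56) and Cyp7b1, of the alternative bile acid pathway (-4.84 ± 0.73), were among the lower members. In the female-biased list, 4 of 17 measured members rose (5 adjusted over the list alone) and 1 fell. The female-biased test gave adjusted p = 0.00133, and adjusted p = 0.220 with an estimated correlation. The periportal list fell, with Etnppl, a phospholyase of ethanolamine phosphate (-4.29 ± 0.63), in front. Among periportal genes, 6 of 23 measured members fell (14 adjusted over the list alone). The periportal test gave adjusted p = 1.74e-06, and adjusted p = 0.327 with an estimated correlation. Pericentral genes moved the other way, as 3 of 19 measured members rose (3 adjusted over the list alone) and 1 fell. The pericentral test gave adjusted p = 0.00569, and adjusted p = 0.504 with an estimated correlation. Without healthy 3 its adjusted p was 0.0826.

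Targets of p53 rose in CDE hepatocytes, led by Eda2r (3.56 ± 0.50). Of these targets, 8 of 23 measured members rose (11 adjusted over the list alone). The p53 test gave adjusted p = 1.33e-04, and adjusted p = 0.327 with an estimated correlation. In the injury and fetal hepatocyte list, 3 of 24 measured members rose (6 adjusted over the list alone), and Anxa2, an annexin (ENSMUSG00000032231, chromosome 9, 69453620 to 69491795), rose by 4.39 ± 0.52. The injury test gave adjusted p = 2.49e-04, and adjusted p = 0.504 with an estimated correlation. In the cell cycle list, 3 of 34 measured members rose (7 adjusted over the list alone). The cell cycle test gave adjusted p = 8.51e-05, and adjusted p = 0.504 with an estimated correlation. Higher members were Ccnd1, a G1 cyclin (3.27 ± 0.28), and the kinetochore gene Casc5 (2.98 ± 0.33). Among YAP targets, 1 of 19 measured members rose (3 adjusted over the list alone). The YAP test gave adjusted p = 0.00133, and adjusted p = 0.356 with an estimated correlation. Among NRF2 and glutathione genes, 3 of 24 measured members rose (4 adjusted over the list alone). The NRF2 test gave adjusted p = 0.00884, and adjusted p = 0.220 with an estimated correlation.

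Among metabolic lists in CDE hepatocytes, cholesterol synthesis fell, including Cyp51 (-2.27 ± 0.37), and 3 of 20 measured members fell (6 adjusted over the list alone). The cholesterol test gave adjusted p = 0.00569, and adjusted p = 0.62 with an estimated correlation. In the bile acid list, 4 of 21 measured members fell (7 adjusted over the list alone). The bile acid test gave adjusted p = 0.0129, and adjusted p = 0.598 with an estimated correlation. Abcc4, an efflux pump of the basolateral membrane (ENSMUSG00000032849, chromosome 14, 118482692 to 118706219), rose instead by 3.11 ± 0.24, from 15.2 ± 2.50 to 131 ± 12.4 CPM. Of methionine, choline and one-carbon genes, 5 of 29 measured members fell (8 adjusted over the list alone). The one-carbon test gave adjusted p = 0.0138, and adjusted p = 0.531 with an estimated correlation. Of lipogenesis genes, 3 of 20 measured members fell (3 adjusted over the list alone). The lipogenesis test gave adjusted p = 0.0236, and adjusted p = 0.630 with an estimated correlation. Of hepatocyte identity genes, 1 of 22 measured members fell (1 adjusted over the list alone). The identity test gave adjusted p = 0.0208, and adjusted p = 0.613 with an estimated correlation. These 4 lists lost their call without healthy 2 or CDE 1, and lipogenesis and identity also without healthy 3. With the empty-droplet profile subtracted, lipogenesis did not pass (adjusted p = 0.0553), and the mitochondrial-encoded and ribosomal lists were lower (0.0161 and 0.0192). With 1 mouse left out, the highest adjusted p values of the bile acid, one-carbon, lipogenesis and identity lists were, in some order, 0.108, 0.0876, 0.210 and 0.119. The other 8 lists did not pass. Their adjusted p values were 0.265 for xenobiotic phase I, 0.438 for fatty acid oxidation, 0.0761 for lipid droplet, 0.372 for acute phase and 0.934 for circadian genes. For unfolded protein and amino acid stress the value was 0.934, with median and test of opposite sign. The RNA quality lists of mitochondrial-encoded and ribosomal protein genes had 0.806 and 0.0688. Some of them passed with 1 mouse left out: lipid droplet without healthy 2, healthy 3 or CDE 3 (adjusted p down to 0.0167), xenobiotic and mitochondrial-encoded genes without CDE 2 (0.0465 and 0.0465), and ribosomal genes without healthy 1, CDE 1, CDE 2 or TAA 1 (down to 5.54e-06). Among single members, Cyp3a13 (-1.76 ± 0.24) and the circadian repressor Nfil3 (-3.65 ± 0.51) fell.

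By edgeR, 983 of 14360 genes differed between CDE and healthy hepatocytes, 474 higher and 509 lower, 942 of them by at least 2-fold. The groups did not overlap for 962 of the 983 and for 29.6% of all genes tested, where chance gives 10%. The other leading higher genes were Slc22a27, of the organic anion transporter family (5.18 ± 0.56), Tinag (5.00 ± 0.60) and the glutathione transferase Gsta1 (4.63 ± 0.40). Other leading lower genes included the urinary protein gene Mup11 (-6.05 ± 1.09) and Cyp2j9 (-5.73 ± 0.65). Without CDE 2 the log2 fold change of Mup11 was -10.20. Marker lists of stellate cells (adjusted p = 0.0024), T and NK cells (0.0232) and cholangiocytes (0.0392) were also higher in these CDE hepatocytes by limma camera, all with adjusted p = 0.891 with an estimated correlation. Free RNA could supply 13.1% to 20.5% of their counts, against 10.97% to 12.7% in healthy hepatocytes, and CDE 1 gave only 105 nuclei. The count was 487 without healthy 1, 457 without healthy 3, 349, 531 and 348 without CDE 1, 2 and 3, and 1507 and 638 without TAA 1 and 3. It was 1910 by DESeq2, 505 with the counts of each mouse thinned to the smallest total, and 615 (325 higher, 290 lower) without a hepatocyte cluster of low marker score described under TAA.

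The comparison of TAA with healthy mice asked the same of the toxin. Hepatocytes of TAA mice had lower periportal, male-biased and identity lists and higher injury, p53 and cell cycle lists. With an estimated correlation no TAA list call held, the lowest adjusted p being 0.131. Gsta1 (ENSMUSG00000074183, chromosome 9, 78230656 to 78242684) rose by 7.72 ± 0.42, from 0.910 ± 0.424 to 211 ± 73.0 CPM (adjusted p = 1.67e-05), and Afp, the fetal liver protein alpha-fetoprotein (ENSMUSG00000054932, chromosome 5, 90490737 to 90508907), by 5.55 ± 0.86, from 1.84 ± 1.59 to 92.1 ± 63.2 CPM (adjusted p = 0.00155). Abcc4 rose by 5.03 ± 0.26, to 496 ± 20.3 CPM (adjusted p = 1.67e-05). Slc1a2, a glutamate transporter of pericentral hepatocytes (ENSMUSG00000005089, chromosome 2, 102658659 to 102790784), changed by -9.64 ± 0.58, from 386 ± 120.5 to 0.717 ± 0.581 CPM (adjusted p = 3.17e-05). TAA 1 had 157 CPM of Afp and 1.38 of Slc1a2, and without it both TAA means moved by over 1.5 times.

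All 21 measured members of the male-biased list fell in TAA (21 adjusted over the list alone), with a median of -5.63. The TAA male-biased test gave adjusted p = 1.01e-12, and adjusted p = 0.131 with an estimated correlation. Members with large falls were Serpina1e (-7.85 ± 0.61), Susd4 (-5.92 ± 0.52) and Slco1a1 (-6.48 ± 0.59). In the female-biased list, 9 of 17 measured members rose (10 adjusted over the list alone) and 1 fell, with Cyp2b9 (6.11 ± 0.51) and Cyp2a4 (8.10 ± 0.82, and 13.24 without healthy 3, the 1 healthy mouse with counts) in front. The TAA female-biased test gave adjusted p = 0.00217, and adjusted p = 0.131 with an estimated correlation. In the periportal list, 19 of 23 measured members fell (21 adjusted over the list alone) and 1 rose, with a median of -2.85. The TAA periportal test gave adjusted p = 1.21e-10, and adjusted p = 0.131 with an estimated correlation. Lower members were the histidine ammonia-lyase gene Hal (-5.04 ± 0.60), Etnppl (-5.67 ± 0.67) and the glutaminase gene Gls2 (-3.40 ± 0.47). Pericentral genes split, with 3 higher and 6 lower of 19 (4 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.364). Glul, the glutamine synthetase of the central vein rim, fell (-3.66 ± 0.42), whereas Nt5e, an ectonucleotidase (ENSMUSG00000032420, chromosome 9, 88327197 to 88372092), rose (5.18 ± 0.58). Of hepatocyte identity genes, 12 of 22 measured members fell (13 adjusted over the list alone), among them the urea cycle gene Otc (-4.19 ± 0.63) and Proc, protein C (-2.43 ± 0.40). The TAA identity test gave adjusted p = 2.40e-06, and adjusted p = 0.215 with an estimated correlation.

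In the cell cycle list, 29 of 34 measured members rose (30 adjusted over the list alone) and none fell in TAA hepatocytes, with a median of 2.85. The TAA cell cycle test gave adjusted p = 1.30e-12, and adjusted p = 0.131 with an estimated correlation. Ccnd1 (2.83 ± 0.27), Casc5 (3.05 ± 0.32) and Bub1b (3.69 ± 0.44) were among the higher members. A cluster led by division genes, Cenpf and Top2a among them, held 290 of the TAA hepatocytes, 10 of the healthy and 8 of the CDE ones, and 67.1% of its nuclei came from TAA 3, so the rise need not be shared by all hepatocytes. In the injury and fetal list, 19 of 24 measured members rose (19 adjusted over the list alone) and 1 fell. The TAA injury test gave adjusted p = 1.65e-06, and adjusted p = 0.266 with an estimated correlation. Tnfrsf12a, the TWEAK receptor (3.92 ± 0.35), Anxa2 (5.35 ± 0.53) and Anxa5 (2.52 ± 0.26) were higher. Of p53 targets, 16 of 23 measured members rose (16 adjusted over the list alone) and 1 fell. The TAA p53 test gave adjusted p = 4.39e-06, and adjusted p = 0.131 with an estimated correlation. Eda2r (5.06 ± 0.50), the death receptor Tnfrsf10b (4.69 ± 0.51) and Psrc1 (5.87 ± 0.66) led the rise. In the NRF2 and glutathione list, 11 of 24 measured members rose (12 adjusted over the list alone) and 3 fell. The TAA NRF2 test gave adjusted p = 6.18e-04, and adjusted p = 0.131 with an estimated correlation. Cbr3 (5.49 ± 0.47), Nqo1, a quinone reductase (3.77 ± 0.41), and Slc7a11, the cystine importer (3.92 ± 0.52), were higher.

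Further lists fell in TAA hepatocytes. In the bile acid list, 12 of 21 measured members fell (13 adjusted over the list alone), among them Slc10a1, the main bile acid importer (-4.27 ± 0.54). Abcc4, another member, rose. The TAA bile acid test gave adjusted p = 6.71e-05, and adjusted p = 0.295 with an estimated correlation. In xenobiotic phase I, 10 of 19 measured members fell (10 adjusted over the list alone) and 1 rose, with the carboxylesterase gene Ces2a lower (-4.14 ± 0.66). The TAA xenobiotic test gave adjusted p = 0.0126, and adjusted p = 0.379 with an estimated correlation. In lipogenesis, 11 of 20 measured members fell (14 adjusted over the list alone), including Pklr, a pyruvate kinase gene (-2.89 ± 0.50), and the carbohydrate-response factor Mlxipl (-2.48 ± 0.46). The TAA lipogenesis test gave adjusted p = 1.86e-05, and adjusted p = 0.295 with an estimated correlation. Of methionine, choline and one-carbon genes, 15 of 29 measured members fell (17 adjusted over the list alone). The TAA one-carbon test gave adjusted p = 2.03e-05, and adjusted p = 0.215 with an estimated correlation. Cbs (-2.84 ± 0.33) and Cth (-4.01 ± 0.50) of transsulfuration and Mat1a, of methionine activation (-2.78 ± 0.45), were lower. In the acute phase list, 12 of 26 measured members fell (14 adjusted over the list alone) and 1 rose, with Itih4 (-2.47 ± 0.22) and the fibrinogen gene Fgg (-2.46 ± 0.33) lower. The TAA acute phase test gave adjusted p = 1.39e-05, and adjusted p = 0.131 with an estimated correlation. In the circadian list, 4 of 16 measured members fell (4 adjusted over the list alone), led by Nfil3 (-3.06 ± 0.47) and Bhlhe40 (-1.77 ± 0.31). The TAA circadian test gave adjusted p = 0.0257, and adjusted p = 0.131 with an estimated correlation.

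The remaining TAA lists did not pass, apart from that of mitochondrial-encoded genes. Cholesterol synthesis had adjusted p = 0.148, and 0.0032 without the low-score cluster described next. Adjusted p values were 0.116 for fatty acid oxidation, 0.873 for lipid droplet, 0.447 for YAP targets and 0.206 for ribosomal protein genes. For unfolded protein and amino acid stress the value was 0.206, with median and test of opposite sign. With 1 mouse left out, cholesterol synthesis passed without healthy 3 (adjusted p = 0.00187), fatty acid oxidation without TAA 2 or TAA 3 (down to 0.0205) and ribosomal genes without healthy 3, TAA 2 or TAA 3 (down to 0.00223). Among their members Ppargc1a, a coactivator of mitochondrial genes, fell (-3.47 ± 0.51), and Hilpda (4.26 ± 0.47) and the fatty acid receptor Cd36 (2.14 ± 0.33) rose. The mitochondrial-encoded list was lower, with a median of -1.14 and no single member past the threshold. The TAA mitochondrial test gave adjusted p = 0.00393, and adjusted p = 0.570 with an estimated correlation. Without TAA 3 its adjusted p was 0.0926.

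By edgeR, 4161 of 14360 genes differed between TAA and healthy hepatocytes, 2293 higher and 1868 lower, 3647 of them by at least 2-fold. The groups were separate for 4025 of these and for 46.6% of all genes tested, where chance gives 10%. Tinag (7.24 ± 0.61) was also among the highest. For genes with 1 to 3 counts in a group, counting ratios with 95% intervals are given. Mup11 was lower by a ratio of 6898 (1238 to 272500), Mup17 by 2808 (503 to 110943), the fatty acid elongase Elovl3 by 1545 (528 to 7497) and the steroid dehydrogenase Hsd3b5 by 1619 (448 to 13374). Cyp1a1 was higher by 230 (78.5 to 1119) and the p53 target Phlda3 by 172 (47.4 to 1429). Hepatocyte markers were lower in TAA hepatocytes (adjusted p = 3.04e-06 by limma camera), with adjusted p = 0.891 with an estimated correlation. Free RNA could supply 46.0%, 35.4% and 29.9% of the hepatocyte counts of TAA 1, 2 and 3. At a doubled clustering resolution 124 nuclei of TAA 1 were named hepatocytes in place of 364, with a free RNA share of 24.0%, and a cluster of 247 nuclei, 98.0% of them from TAA 1 and with 86.7% free RNA, was left unnamed. The class of most TAA 1 hepatocytes is thus uncertain, and 4401 genes differed at that resolution, 2301 higher and 2100 lower. Hepatocytes of the 3 groups lay in nearly separate clusters, several of them almost wholly from 1 mouse, such as clusters with 99.8% of nuclei from healthy 3, 97.8% from healthy 2 and 94.8% from CDE 3. A cluster with a low hepatocyte score, led by Slc7a11, Ehhadh and Gsta1, held 48.5% and 62.1% of the hepatocytes of TAA 2 and 3, 0.275% of TAA 1 and none of the healthy mice. Without it 2254 genes differed, 1335 higher and 919 lower. The count was 2730 without healthy 3, 2557 without TAA 3, and 1645 with the counts thinned to the smallest total, when 693 were higher and 952 lower.

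The direct comparison of both exposures asked where they differed. TAA hepatocytes had more Afp (6.06 ± 1.03, adjusted p = 0.00891), a call that ended without CDE 3 (0.0611). They had more Nt5e (3.74 ± 0.56, adjusted p = 0.00498), with 216 ± 27.4 against 13.3 ± 14.1 CPM, a CDE mean that CDE 3 carried with 29.6. Gsta1 (3.09 ± 0.34), the scaffold gene Grip1 (4.35 ± 0.51) and Slc7a11 (3.16 ± 0.52) were higher too, the last with adjusted p = 0.208 without the low-score cluster. Slc1a2 was far lower in TAA than in CDE (-7.98 ± 0.56, adjusted p = 4.29e-04). Elovl3 was lower by a counting ratio of 96 (30.9 to 481), and Mup2 (-4.96 ± 1.10), Slc22a28 (-4.92 ± 0.98) and the methyltransferase gene Inmt (-4.40 ± 0.89) also fell. Those 4 calls ended without TAA 3 and, Slc22a28 apart, without CDE 2, and that of Elovl3 also without TAA 2. The calls of Elovl3, Mup2 and Inmt also ended without the low-score cluster, and those of Elovl3, Mup2 and Slc22a28 after thinning to the smallest total. Without CDE 2 the log2 fold change of Slc22a28 was -2.71. Over all alternatives run the highest adjusted p values of the 4 were 0.203, 0.0951, 0.0654 and 0.0616.

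Cell cycle genes were higher in TAA than in CDE, where 9 of 34 measured members rose (14 adjusted over the list alone). The cell cycle test gave adjusted p = 1.39e-07, and adjusted p = 0.317 with an estimated correlation. Of injury and fetal genes, 8 of 24 measured members rose (15 adjusted over the list alone). The injury test gave adjusted p = 4.43e-04, and adjusted p = 0.358 with an estimated correlation. Of cholesterol synthesis genes, 9 of 20 measured members rose (14 adjusted over the list alone). The cholesterol test gave adjusted p = 1.30e-04, and adjusted p = 0.358 with an estimated correlation. Of p53 targets, 3 of 23 measured members rose (11 adjusted over the list alone). The p53 test gave adjusted p = 3.24e-04, and adjusted p = 0.317 with an estimated correlation. Of NRF2 and glutathione genes, 6 of 24 measured members rose (9 adjusted over the list alone) and 2 fell. The NRF2 test gave adjusted p = 0.0295, and adjusted p = 0.317 with an estimated correlation. Of acute phase genes, 11 of 26 measured members fell (13 adjusted over the list alone). The acute phase test gave adjusted p = 7.31e-07, and adjusted p = 0.279 with an estimated correlation. Of periportal genes, 5 of 23 measured members fell (7 adjusted over the list alone). The periportal test gave adjusted p = 1.67e-07, and adjusted p = 0.312 with an estimated correlation. Of male-biased genes, 7 of 21 measured members fell (13 adjusted over the list alone). The male-biased test gave adjusted p = 3.64e-06, and adjusted p = 0.312 with an estimated correlation. Of one-carbon genes, 8 of 29 measured members fell (10 adjusted over the list alone). The one-carbon test gave adjusted p = 4.44e-04, and adjusted p = 0.346 with an estimated correlation. Without the low-score cluster the NRF2 list had adjusted p = 0.260 and the one-carbon list 0.0537.

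Further lists lower in TAA than in CDE were hepatocyte identity (adjusted p = 3.53e-05), pericentral (3.24e-04), lipogenesis (7.24e-04), bile acid (0.00159), circadian (0.00857) and mitochondrial-encoded genes (9.18e-04). Ribosomal protein genes were higher (0.00146). With an estimated correlation these 7 lists had adjusted p = 0.346, 0.358, 0.358, 0.358, 0.279, 0.422 and 0.552. Xenobiotic (0.0332), stress (0.0332) and YAP target lists (0.0295) were lower as well, with adjusted p = 0.443, 0.358 and 0.358 with an estimated correlation. The xenobiotic call ended without CDE 2 or TAA 1 (adjusted p up to 0.346) and the stress call without CDE 1, CDE 3 or TAA 3 (up to 0.270), and both ended without the low-score cluster (0.146 and 0.139). With calling as first written the xenobiotic list had adjusted p = 0.0524. The YAP call ended without CDE 1, CDE 2, TAA 2 or TAA 3 (up to 0.252) and with the empty-droplet profile subtracted (0.156), the mitochondrial-encoded call without CDE 2 or TAA 3 (up to 0.0725) and the ribosomal call without CDE 3 (0.234). Fatty acid oxidation (0.123), lipid droplet (0.336) and female-biased genes (0.491) did not pass, and the lipid droplet median and test had opposite signs. Fatty acid oxidation passed without CDE 3, TAA 2 or TAA 3 (adjusted p down to 0.0124).

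By edgeR, 1442 genes differed between TAA and CDE hepatocytes, 781 higher and 661 lower in TAA. The groups were separate for 1425 of these and for 34.3% of all genes tested, where chance gives 10%. Stellate markers (adjusted p = 8.65e-04 by limma camera) and hepatocyte markers (5.63e-07) were lower in TAA than in CDE hepatocytes, both with adjusted p = 0.891 with an estimated correlation. The count was 307 (169 higher, 138 lower) without the low-score cluster, 603 after thinning to the smallest total and 2279 by DESeq2. It was 487 and 313 without CDE 2 and 3, and 843 and 324 without TAA 2 and 3.

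**Figure D1:**
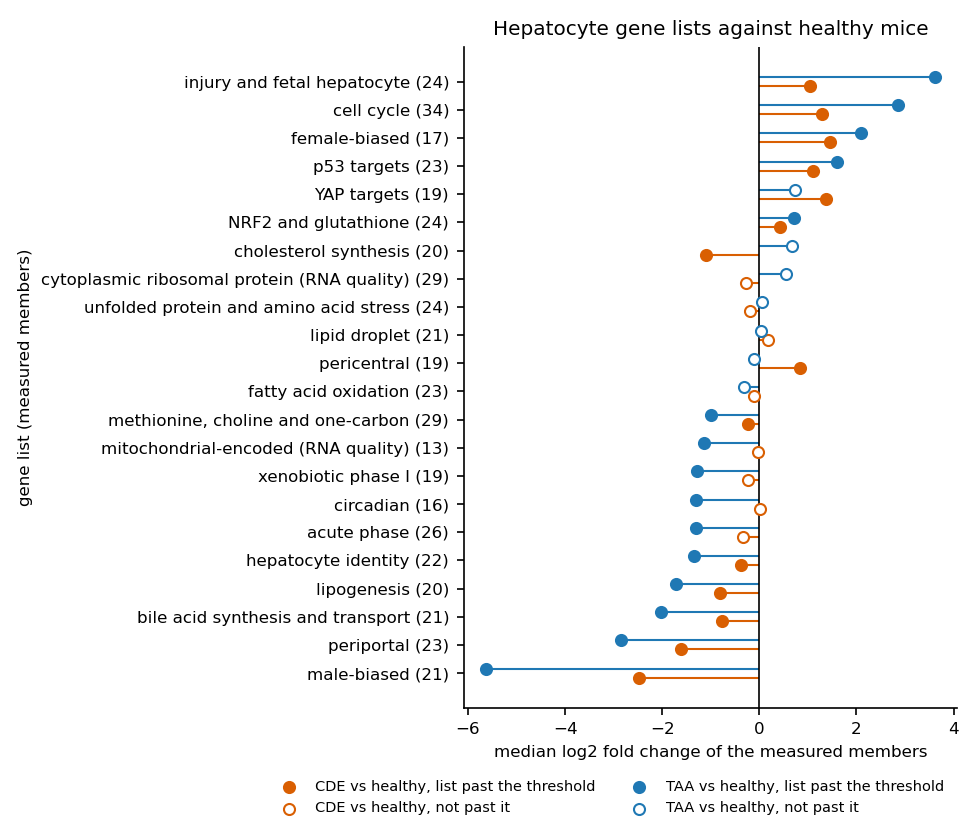
Median log2 fold change of the measured members of each hepatocyte gene list (y axis, with the number of members) in CDE and in TAA against healthy mice (x axis); filled points are lists past the threshold by limma camera and open points lists that did not pass. The male-biased list lies lowest in both, at -2.48 in CDE and -5.63 in TAA, and the injury and fetal list highest in TAA, at 3.61.

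Across all 9 mice, 4047 of 14360 hepatocyte genes differed among the 3 groups by edgeR, with 2261 without TAA 3, 2165 without the low-score cluster and 1629 after thinning to the smallest total. CDE and TAA effects against healthy mice moved together across genes: 338 genes were higher in both, where independent calls would give 75.7, 363 were lower in both, against 66.2, and 18 were called in opposite directions. The independent values do not allow for the shared healthy mice. With 1 mouse left out, 133 (without CDE 3) to 422 (without TAA 1) genes were higher in both. From 93 (without CDE 1) to 485 (without TAA 1) were lower in both, and 3 to 26 were opposite. The covariance of both sets of log2 fold changes was 0.999, against 0.116 ± 0.00353 (SD, 30 simulations) for unchanged groups that shared 3 simulated healthy libraries, a difference of 0.883. All 9 libraries were redrawn gene by gene, so shifts of many genes in 1 mouse were not simulated and the SD does not cover them. With 1 mouse left out the covariance ran from 0.855 to 1.20. Pearson's r was 0.572 and Spearman's rho 0.575 across genes, which are not independent replicates, with a simulated r of 0.441 from the shared controls alone. The 3 controls were too few to be divided between the comparisons.

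Endothelial nuclei of TAA mice had lower sinusoidal genes, as 11 of 15 measured members fell (13 adjusted over the list alone), with a median of -1.16. The sinusoidal test gave adjusted p = 1.78e-04, and adjusted p = 0.523 with an estimated correlation. Dnase1l3, a secreted nuclease (-1.90 ± 0.17), Oit3 (-1.29 ± 0.22) and Clec4g (-1.19 ± 0.20) fell. The scavenger receptor gene Stab2 fell (-1.41 ± 0.20), to 2978 ± 345 from 7937 ± 1231 CPM. Of the 11 lower members 8 were still called with the empty-droplet profile subtracted and 8 with scaling on the genes tested, with Stab2, Oit3 and Clec4g at -0.88, -0.77 and -0.67 after subtraction. Ednrb, an endothelin receptor (ENSMUSG00000022122, chromosome 14, 103814625 to 103844402), rose by 2.13 ± 0.29 (adjusted p = 0.00199), to 216 ± 43.4 from 49.2 ± 7.51 CPM. The BMP modulator Bmper (1.86 ± 0.30) and Abi1 (1.56 ± 0.41) rose, the latter with adjusted p up to 0.0602 without healthy 2 or TAA 1. Pla2r1 (-2.21 ± 0.35), Ehd3 (-2.00 ± 0.24) and Rasgrf2 (-1.94 ± 0.37) fell. An endothelial cluster that held 52.4% of the healthy and 53.2% of the CDE nuclei held 1.20% of the TAA nuclei, while 90.6% of the TAA nuclei lay in another. The angiocrine (adjusted p = 0.118) and capillarization lists (0.113) did not pass in TAA, each with median and test of opposite sign. In CDE the sinusoidal list was lower with no member past the threshold. The CDE sinusoidal test gave adjusted p = 0.00386, and adjusted p = 0.549 with an estimated correlation. The angiocrine (0.212) and capillarization lists (0.212) did not pass in CDE. Angiocrine genes passed without CDE 3 in CDE (0.0253), and capillarization genes without healthy 2 or CDE 3 in CDE (down to 0.0460) and without healthy 2 in TAA (0.0306). With the empty-droplet profile subtracted the angiocrine list was higher in CDE and in TAA (adjusted p = 0.0395 each).

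Stellate and mesenchymal nuclei, the matrix-producing cells of the liver, had lower quiescence genes in TAA, where 12 of 19 measured members fell (13 adjusted over the list alone). The TAA quiescence test gave adjusted p = 4.85e-04, and adjusted p = 0.523 with an estimated correlation. Vipr1 (-1.81 ± 0.21), Pth1r (-1.71 ± 0.23), Reln (-0.97 ± 0.16) and Ecm1 (-1.72 ± 0.31) were lower. All stellate genes tested had a median of -0.37, with -0.36 expected from free RNA at its largest possible shares. Of the 12 lower members 5 were still called with the empty-droplet profile subtracted, with Reln at -0.53, and 6 with scaling on the genes tested. Scube1, a secreted EGF-domain protein (ENSMUSG00000016763, chromosome 15, 83604999 to 83725021), rose by 4.08 ± 0.43 (adjusted p = 7.18e-04), to 209 ± 60.6 from 12.6 ± 2.93 CPM. Ankrd55 (3.28 ± 0.42) and Dkk3 (2.26 ± 0.37) also rose, while Egfem1 (-3.47 ± 0.52), Grid1 (-3.44 ± 0.60) and Rgs7 (-3.40 ± 0.53) fell. The groups lay largely in different stellate clusters: 1 cluster held 80.4% of the healthy nuclei, another 63.1% of the CDE nuclei, and 1 more, with Scube1 and Ankrd55 among its top genes, 76.7% of the TAA, 15.2% of the CDE and 2.58% of the healthy nuclei. Of activation and matrix genes, 2 of 22 measured members fell (1 adjusted over the list alone) in TAA, neither of them called after subtraction, and the list did not pass (adjusted p = 0.102, 0.0223 without healthy 2 and 0.0199 with the empty-droplet profile subtracted), with median and test of opposite sign. In CDE the activation list was higher and quiescence lower, with no member of either past the threshold over all genes. The CDE activation test gave adjusted p = 0.00269, and adjusted p = 0.523 with an estimated correlation. The CDE quiescence test gave adjusted p = 0.00827, and adjusted p = 0.523 with an estimated correlation. The activation call ended without healthy 1 or CDE 1 (adjusted p up to 0.330) and the quiescence call without CDE 3 (0.127).

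Macrophages of TAA mice had lower resident Kupffer cell genes, where 5 of 15 measured members fell (9 adjusted over the list alone). The TAA Kupffer test gave adjusted p = 2.99e-04, and adjusted p = 0.523 with an estimated correlation. C6 (-1.79 ± 0.33), the phosphatidylserine receptor gene Timd4 (-2.08 ± 0.39), Cdh5 (-1.72 ± 0.33) and Cd163 (-1.61 ± 0.37) were among the lower members. With the empty-droplet profile subtracted 3 of these 5 members were still called, and Cd163 was not (adjusted p = 0.0583). The monocyte and lipid-associated list was higher, with Lgals3, a galectin, as its 1 of 7 members past the threshold (1.74 ± 0.33). The TAA monocyte test gave adjusted p = 0.0134, and adjusted p = 0.523 with an estimated correlation. Without healthy 1 its adjusted p was 0.0595, and the rule for free RNA, which keeps a gene more readily when it is high in TAA nuclei, left 7 of its 23 members, a choice that leans towards a rise. This class held 1 cluster, led by Kupffer cell genes, and not the unnamed monocyte-like cluster led by Gpr141, Adgre4, Rap1gap2 and F13a1, so these values leave that cluster out. They also leave out an unnamed cluster led by Cd5l and Vsig4, where macrophage (0.69) and endothelial scores (0.66) were close. That cluster made up a mean of 1.45% of TAA, 0.564% of CDE and 0.337% of healthy nuclei, with 0.312% in TAA 2. Sh3pxd2b (3.16 ± 0.48), Tenm4 (2.95 ± 0.45) and Atp8b4 (2.72 ± 0.43) rose and Adgre4 (-2.15 ± 0.36) and Slc11a1 (-1.95 ± 0.46) fell. None of these single-gene calls held without TAA 3 or with the replicate block, and no macrophage gene was called in TAA in either setting or without healthy 2. Slc11a1 was at -0.98 without healthy 2, and its call ended with the empty-droplet profile subtracted (adjusted p = 0.0511). With calling as first written the calls of Lgals3 (0.0639) and Atp8b4 (0.683) ended, with Atp8b4 at 0.25. In CDE the Kupffer list was lower and the monocyte list higher, with no member of either past the threshold. The CDE Kupffer test gave adjusted p = 1.68e-06, and adjusted p = 0.523 with an estimated correlation. The CDE monocyte test gave adjusted p = 0.00121, and adjusted p = 0.523 with an estimated correlation. Sh3pxd2b was the 1 gene called in CDE (3.66 ± 0.47, adjusted p = 0.0263), a call that ended without healthy 1, healthy 2, CDE 1, CDE 3, TAA 2 or TAA 3 and with the replicate block (up to 0.343 over all alternatives run).

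In cholangiocytes of TAA mice Top2a, a topoisomerase of dividing cells (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189), was higher by a counting ratio of 59.5 (20.2 to 290.1) on 289 against 3 UMIs (adjusted p = 1.31e-04). Mki67 rose by 4.49 ± 0.69 and the formin gene Diaph3 by 3.89 ± 0.60. A cluster with Top2a among its top genes held 17.4% of the TAA, 0.187% of the CDE and none of the healthy cholangiocytes. Taco1 (4.23 ± 0.83) and the adhesion gene Vcam1 (2.63 ± 0.51) rose and Adam33 (-3.12 ± 0.44), Ddit4l (-2.75 ± 0.31) and Dtna (-2.55 ± 0.39) fell. The reactive cholangiocyte list did not pass in TAA (adjusted p = 0.727) or in CDE (0.0789, and down to 0.00914 without CDE 2 or CDE 3). In TAA 2 of its 15 members rose and 4 fell (2 and 5 adjusted over the list alone), and Krt19 fell (-2.14 ± 0.46, adjusted p = 0.124 without healthy 3). In CDE cholangiocytes the 1 gene called was Basp1 (2.69 ± 0.36, adjusted p = 0.0263), which the rule for named genes did not take and which is named after its value was seen. That call ended without healthy 2, healthy 3, CDE 1, CDE 3, TAA 2 or TAA 3, with the replicate block, after thinning and with nuclei of at least 2000 UMIs.

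By edgeR, TAA differed from healthy mice in 439 of 1454 endothelial genes (31 higher, 408 lower) and 523 of 2213 stellate genes (44 and 479), after genes that free RNA could supply were left out. It differed in 74 of 1137 macrophage genes (16 and 58) and 451 of 2111 cholangiocyte genes (136 and 315). CDE differed in 0 of 3229 endothelial genes (254 at an unadjusted p under 0.05, and 18 by DESeq2) and 0 of 7492 stellate genes (381, near the number that chance gives, and 10 by DESeq2). It differed in 1 of 2610 macrophage genes and 1 of 6611 cholangiocyte genes. Of genes changed 2-fold in simulated CDE data, 9% were found in endothelial and 14% in stellate nuclei, so changes of that size would mostly be missed. The simulation also held genes that free RNA could supply (9608 and 10716 genes), so its shares need not be those of the genes tested here. Free RNA could supply 44.8% of the endothelial counts in TAA against 24.0% in healthy mice, 34.2% against 15.8% for stellate cells, 46.2% against 26.4% for macrophages and 33.5% against 14.3% for cholangiocytes. The median log2 fold change of all genes tested was -0.50, -0.37, -0.40 and -0.24. With the empty-droplet profile subtracted the TAA counts were 176 (54 higher, 122 lower), 239 (111 and 128), 50 (35 and 15) and 296 (173 and 123). Scaled on the genes tested they were 200 (86 and 114), 248 (118 and 130), 90 (55 and 35) and 438 (225 and 213), so the split between higher and lower genes depended on the scaling. The endothelial TAA count was 222 without healthy 3, 283 without TAA 2 and 272 without TAA 3, and the cholangiocyte count 165, 297 and 226 without the same mice. The macrophage TAA count was 36 without healthy 1, 0 without healthy 2 or TAA 3, 33 without CDE 1 or CDE 2 and 8 without TAA 2. For CDE, 1 stellate gene was called without healthy 3 or CDE 2. The CDE macrophage count was 4 without CDE 2 and 0 without healthy 1, healthy 2, CDE 1, CDE 3, TAA 2 or TAA 3. The CDE cholangiocyte count was 3 without healthy 2, 2 without CDE 2 or TAA 1 and 0 without healthy 3, CDE 1, CDE 3, TAA 2 or TAA 3. Macrophages lacked healthy 3 (18 nuclei) and cholangiocytes healthy 1 (11 nuclei), which left 2 healthy mice for each.

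**Figure D2:**
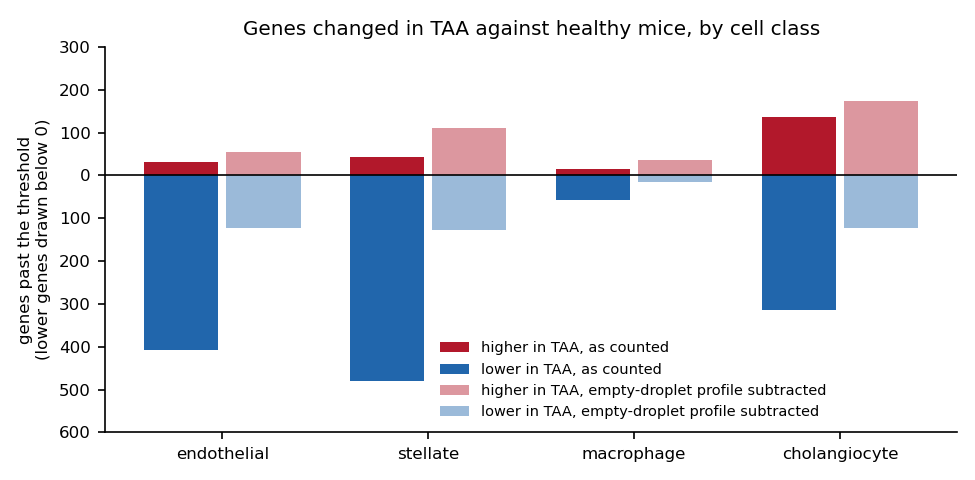
Number of genes past the threshold in TAA against healthy mice for 4 cell classes (x axis), with higher genes above 0 and lower genes below 0 on the y axis, as counted and after the empty-droplet profile was subtracted. Lower genes fell in number with subtraction, from 408 to 122 in endothelial nuclei and from 479 to 128 in stellate nuclei.

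The shares of cell classes among nuclei were compared to ask whether the exposures changed liver composition. Stellate nuclei made up 17.2% ± 7.26 (SD, n = 3) in healthy, 30.7% ± 11.8 in CDE and 12.2% ± 2.39 in TAA mice, and dendritic cells 0.736% ± 0.532, 4.40% ± 1.09 and 2.85% ± 0.419. Hepatocytes made up 44.3% ± 22.9, 12.8% ± 16.1 and 39.2% ± 8.52, cholangiocytes 2.26% ± 1.76, 12.0% ± 17.3 and 5.37% ± 1.72, and macrophages 1.97% ± 1.95, 4.06% ± 1.87 and 8.56% ± 7.91. Endothelial nuclei made up 18.6%, 14.5% and 14.4%, T and NK cells 3.83%, 6.68% and 3.56%, B and plasma cells 6.95%, 6.76% and 2.23%, and mesothelial cells 1.11%, 1.00% and 0.377%. Single mice carried several means: CDE 3 had 31.2% hepatocytes and CDE 1 32.0% cholangiocytes and 2.24% mesothelial cells. TAA 1 had 25.3% endothelial nuclei and 17.5% macrophages, TAA 2 had 3.72% B and plasma cells and healthy 1 had 4.10% macrophages. Healthy 2 had 6.82% T and NK, 11.6% B and plasma and 1.89% mesothelial cells, and each of these means moved by over 1.5 times without that mouse. By an exact permutation test over the 280 splits of 9 mice, none of the 9 classes differed after adjustment; the smallest p was 0.00714 for dendritic cells (adjusted p = 0.0643, or 0.143 among non-hepatocyte nuclei), then 0.0536 for stellate cells and 0.107 for hepatocytes. These shares depend on nucleus isolation, on the sort and on calling, and 3 mice against 3 cannot give a p below 0.1. In TAA 1 only barcodes of at least 1203 UMIs were called, while the test added shallower nuclei in the other libraries. Its share of B and plasma cells, whose cluster had a median of 853 UMIs, was 0.162% and may be low through calling. The other TAA 1 shares are affected too.

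The share of hepatocyte nuclei in which a gene was detected, among nuclei of at least 1000 UMIs thinned to 1000, described how widely injury and zonation genes were carried. Endothelial nuclei are given for comparison, at the same depth. Nuclei below that depth were left out: 81 healthy and 89 CDE hepatocytes. Of endothelial nuclei, 784 of 3076 healthy, 924 of 2308 CDE and 161 of 1338 TAA ones were left out. Cdkn1a, the p53-induced cell cycle inhibitor, was detected in 0.457% ± 0.257 in healthy, 5.07% ± 4.27 in CDE and 13.2% ± 2.75 in TAA mice (SD, n = 3, adjusted p = 0.0143, exact permutation test), against 0.660% ± 0.203, 1.14% ± 0.188 and 8.85% ± 0.645 in endothelial nuclei. Abcc4 was detected in 1.42% ± 0.509, 9.61% ± 2.20 and 30.9% ± 1.81 of hepatocytes (exact adjusted p = 0.0143), against 20.6% ± 2.89, 18.8% ± 1.96 and 26.5% ± 1.49 in endothelial nuclei. Mdm2, the p53 regulator, was found in 7.34% ± 1.72, 13.2% ± 4.98 and 23.5% ± 1.80 (exact adjusted p = 0.0143), against 6.91% ± 0.778, 6.51% ± 0.468 and 15.0% ± 2.73. Gpc3, a fetal liver glypican, was found in 0.195% ± 0.221, 0.741% ± 0.357 and 6.44% ± 1.18 (exact adjusted p = 0.0143), against 0.406% ± 0.204, 0.504% ± 0.208 and 2.78% ± 1.07. Hal fell from 39.6% ± 18 to 20% ± 7.27 and 4.15% ± 1.37 (exact adjusted p = 0.0257), against 8.26% ± 2.18, 5.50% ± 6.67 and 1.93% ± 1.07 in endothelial nuclei. The periportal Cyp2f2 fell from 41.2% ± 13 to 18.1% ± 10.5 and 10.5% ± 2.82 (exact adjusted p = 0.0238), against 9.14% ± 1.28, 7.69% ± 5.18 and 6.12% ± 3.45. The pericentral Cyp2e1 was found in 18.5% ± 8.23, 46.9% ± 7.15 and 7.30% ± 5.05 (exact adjusted p = 0.0143), against 13.5% ± 7.78, 25.7% ± 10.1 and 4.31% ± 3.98. Glul was found in 6.51% ± 2.25, 10.4% ± 2.35 and 1.68% ± 0.927 (exact adjusted p = 0.0143), against 8.38% ± 2.18, 5.67% ± 2.01 and 4.59% ± 0.473. CDE 1 had 9.90% for Cdkn1a, healthy 2 had 0.436% for Gpc3 and TAA 2 had 13.1% for Cyp2e1, and each of these means moved by over 1.5 times without that mouse.

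Afp was detected in 0.0985% ± 0.0853, 0.0221% ± 0.0383 and 8.55% ± 7.5 of hepatocytes (exact adjusted p = 0.0214), against 0% ± 0, 0.0443% ± 0.0767 and 6.17% ± 4.21 in endothelial nuclei. Anxa2 was found in 0.235% ± 0.176, 4.53% ± 0.806 and 10.1% ± 6.43 (exact adjusted p = 0.0184), against 4.42% ± 0.772, 5.11% ± 1.01 and 6.61% ± 3.51. Top2a was found in 0.0878% ± 0.05, 1.23% ± 1.51 and 3.47% ± 1.40 (exact adjusted p = 0.0429), against 0.173% ± 0.171, 0.244% ± 0.314 and 1.82% ± 0.852. Mki67 was found in 0.0958% ± 0.0201, 1.01% ± 1.70 and 2.09% ± 0.954, against 0.0298% ± 0.0517, 0.0885% ± 0.153 and 1.01% ± 0.36, and did not pass (exact adjusted p = 0.136), which left 11 of 12 genes. In healthy and CDE mice Abcc4 and Anxa2 were detected in a larger share of endothelial than of hepatocyte nuclei, so endothelial nuclei do not show the level of free RNA for those genes. The same held for Glul in healthy and TAA mice. The healthy shares of Cdkn1a, Gpc3 and Top2a and the CDE share of Afp lay below the endothelial ones too. Endothelial expression and free RNA cannot be told apart there, so these low shares may be background. The count was 6 without healthy 3, CDE 2, CDE 3, TAA 1, TAA 2 or TAA 3, and 7 without the low-score cluster. Thinned to 2000 UMIs, Mki67 passed (exact adjusted p = 0.0273) and Top2a did not (0.0893), and without thinning Mki67 passed (0.0238) and Cyp2e1 did not (0.0536). With doublets kept neither Mki67 nor Top2a passed (exact adjusted p = 0.075 each), and with calling as first written all 12 genes did (0.0357 for Mki67). Without the low-score cluster Cdkn1a and Hal (exact adjusted p = 0.0524 each), Cyp2f2 (0.107) and Anxa2 (0.121) did not pass. The TAA share was then 18.8% ± 11.4 for Abcc4, 4.12% ± 2.89 for Gpc3, 6.39% ± 1.30 for Hal, 18.3% ± 9.67 for Cyp2f2, 5.77% ± 3.93 for Top2a and 4.23% ± 3.35 for Mki67, and the CDE share of Afp was 0.0443% ± 0.0767. CDE 1 had 2.97% each for Mki67 and Top2a, TAA 1 had 17.03% for Afp, CDE 3 had 0.0664% for Afp and healthy 2 had 0.436% for Anxa2, and each of these means moved by over 1.5 times without that mouse. For Afp, TAA 2 and 3 had 2.79% and 5.83%, against 2.74% and 4.90% in their endothelial nuclei. The class of most TAA 1 hepatocytes was uncertain, as given above, and the detection shares were not repeated at the doubled clustering resolution. Median depth before thinning was 4222, 3211 and 6702 UMIs in hepatocytes and 1388.5, 1153.5 and 1503.5 in endothelial nuclei.

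**Figure D3:**
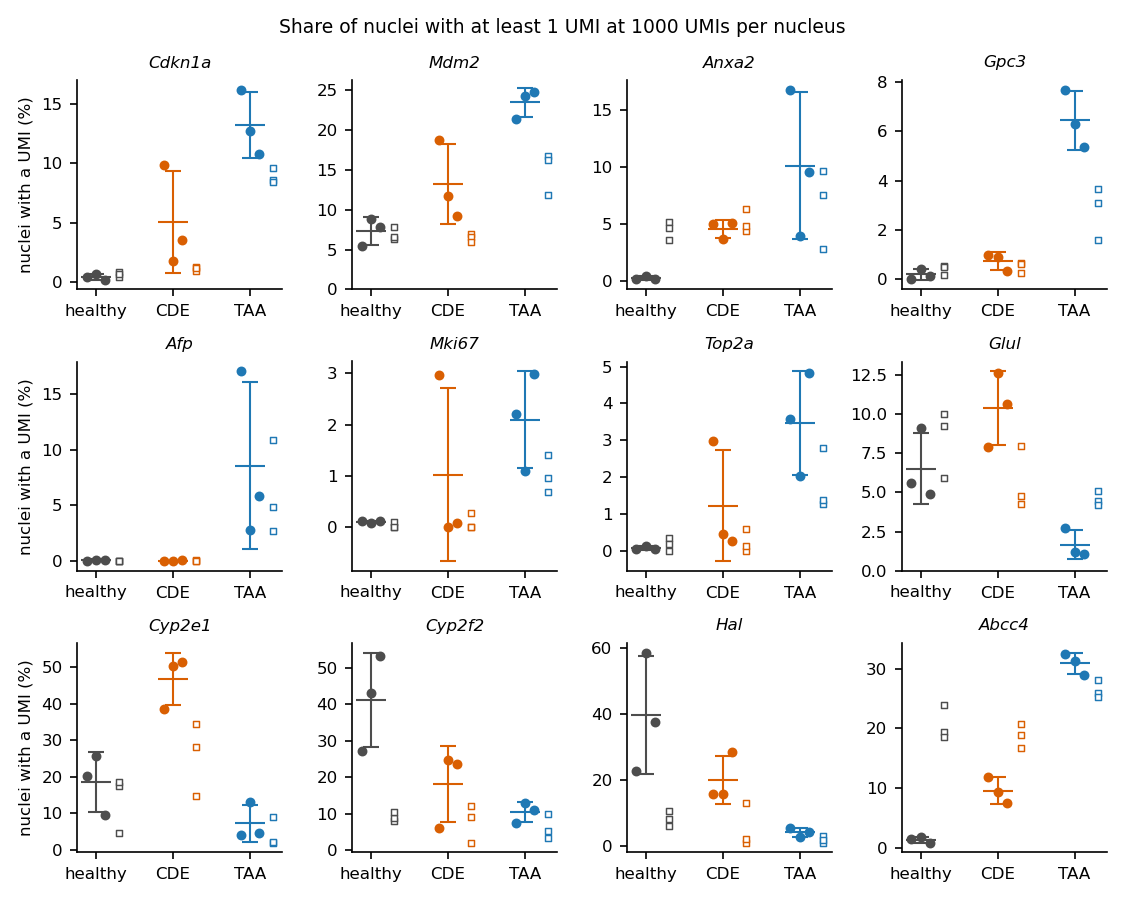
Share of nuclei with at least 1 UMI of each of 12 genes (y axis, percent, a scale per gene) after thinning to 1000 UMIs, by group (x axis): filled circles are the hepatocyte nuclei of 1 mouse, bars the mean ± SD (n = 3) and open squares the endothelial nuclei of 1 mouse. Cdkn1a lies between 10.8% and 16.2% in TAA hepatocytes and between 0.215% and 0.726% in healthy ones.

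Zonation, the division of labour between hepatocytes along the lobule, was measured as the correlation between pericentral and periportal UMIs across the nuclei of each mouse. It was -0.368 ± 0.185 (SD, n = 3) in healthy, -0.296 ± 0.0971 in CDE and 0.0137 ± 0.0638 in TAA mice (p = 0.0321, exact permutation test, 280 splits). The TAA mean lay near 0, with 0.0599, -0.0591 and 0.0401 in TAA 1, 2 and 3. Its size depended on each mouse, and its sign turned without TAA 1. Depth was equal but the zonation UMIs were not, as Hal was detected in 4.15% of TAA against 39.6% of healthy nuclei. A correlation of such low counts can lie near 0 with or without zonation. The pericentral list also held Nt5e, which rose in TAA. Loss of zonation and loss of the measured UMIs therefore cannot be told apart here. The p rose above 0.05 without healthy 1 (0.075), healthy 2 (0.0714), CDE 2 (0.0571), CDE 3 (0.0607), TAA 1 (0.118), TAA 2 (0.0679) or TAA 3 (0.111), without thinning (0.0571) and without the low-score cluster (0.0857). It was also above 0.05 with doublets kept. The limit for injury-list UMIs was the 99th percentile of the hepatocyte nuclei of all healthy mice for an exposed mouse, and of the other healthy mice for a healthy one, so that it could differ between mice. The share of nuclei above it was 1.79% ± 3.04, 5.54% ± 2.93 and 17.3% ± 14.8, with 5.30% in healthy 2 and 33.8% in TAA 1, without which these means moved by over 1.5 times, and it did not pass (p = 0.0571, exact permutation test); it was 0.0143 with the 95th percentile, 0.0107 without TAA 2 and 0.207 without TAA 1. Over all healthy mice the limit lay at 2 UMIs, with 2902 of 5339 TAA nuclei within 1 UMI of it, and free RNA, which differed between the groups, enters both measures. The class of most TAA 1 hepatocytes was uncertain, as given above, and neither measure was repeated at the doubled clustering resolution.

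**Figure D4:**
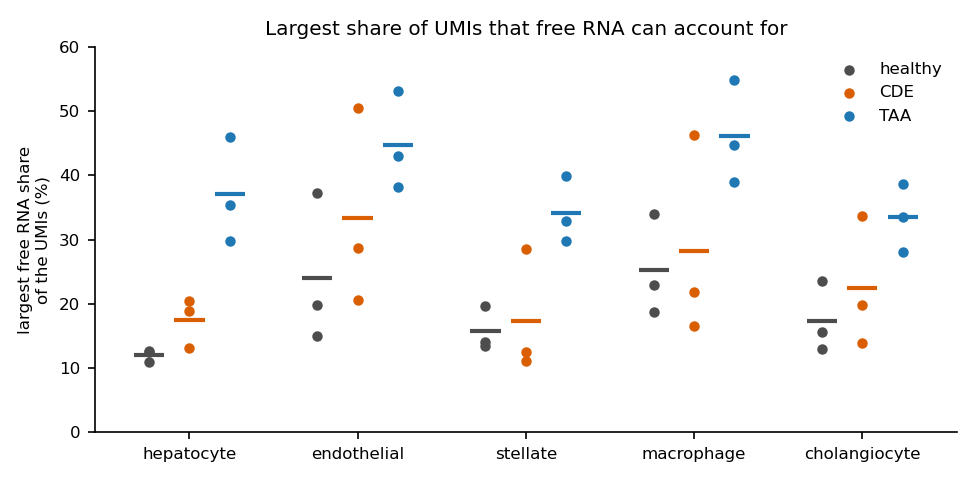
Largest share of UMIs that free RNA could account for in each cell class (x axis) and mouse (points, y axis in percent), with the mean of each group as a line. TAA hepatocytes lie between 29.9% and 46.0%, above all healthy ones, which lie between 10.97% and 12.7%.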

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

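The tests of the 3 patterns weighed here and the counts of other splits were written down only after the results they measure had been seen, and some were changed on the way: the free RNA test of the first pattern had 3 earlier forms, its depth test first counted all 693 higher genes after thinning, and the second pattern was first read from the median after subtraction.

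Empty droplets, which no comparison used, were looked at by group. The barcode ranked 20000 in each library, an empty droplet, held a mean of 641.3 UMIs in TAA mice against 295 in healthy mice, and every TAA mouse was above every healthy one. TAA 2 and 3 also had the largest libraries (79287535 and 85740692 UMIs, at most 38079016 in healthy mice), and relative to the library total the TAA and healthy values overlapped. An unnamed cluster whose leading genes were Gpr141, Adgre4, Rap1gap2 and F13a1 was nearest to macrophages and monocytes. It made up a mean of 2.89% of CDE and 3.07% of TAA nuclei against 0.630% of healthy ones, with every exposed mouse above every healthy mouse. For 1 exposure against healthy mice, chance separates 3 mice from 3, in either direction, in 10% of comparisons. The separation of both exposures together was not tested. Groups of 3 were not tested for single mice that stand apart.

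The first pattern is the 2293 hepatocyte genes higher in TAA than in healthy mice. Free RNA as the whole cause would not leave the 1855 genes still called higher with the empty-droplet profile subtracted; of the 438 others 118 were no longer tested, and 320 had a median log2 fold change of 1.76 before and 1.80 after and a median SE of 0.527 and 0.725, so that their call ended with the larger error (earlier forms gave 15.4% of the genes above the empty-droplet level in each mouse, 62.5% in the group mean, and 80.9% kept). Unequal depth as the whole cause would not leave the 549 genes still called after thinning to the smallest total; of the 1744 others 1499 were no longer tested, and 245 went from a median of 1.02 to 1.10 with a median SE of 0.277 and 0.486. Nuclei of the low-scoring cluster as the whole cause would not leave the 1284 genes still called without it; of the 1009 others 163 were no longer tested, and 846 went from a median of 1.49 to 1.18 with a median SE of 0.429 and 0.475. For the genes no longer called, each of these sources and a response of hepatocytes to TAA cannot be told apart: with free RNA and depth the median fold did not fall and the calls ended with larger errors or untested genes, while without the cluster the fold itself fell and the SE changed little, which either source would give; for the others a response to the exposure stays open as a hypothesis.

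The second pattern is the excess of lower genes in other cell classes of TAA mice. Free RNA from other cells may dilute a class's own transcripts. The largest shares that free RNA could account for in TAA and healthy mice give an expected log2 shift. It was -0.46 (endothelial), -0.36 (stellate), -0.45 (macrophage) and -0.37 (cholangiocyte), and the median of all genes tested was -0.50, -0.37, -0.40 and -0.24. After subtraction the median was -0.08, -0.02, -0.02 and 0.08, and 108, 119, 12 and 115 of the lower genes were still called, 26.5%, 24.8%, 20.7% and 36.5% of them. Scaling on the genes tested, with no RNA removed, gave medians of 0.01, 0.03, 0.03 and 0.01. A median near 0 after subtraction thus does not by itself show dilution. Whether the other calls ended through a smaller fold or a larger error was not examined. Dilution stays a candidate source of the excess, of unsettled extent, while the genes that stayed lower leave a response of these cells to TAA open.

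The third pattern is lower male-biased and higher female-biased genes in hepatocytes of exposed mice. Female mice among the exposed would lack Ddx3y, a gene of the Y chromosome, but its lowest value over the 9 mice was 66.7 CPM, and the female transcript Xist reached at most 3.39 CPM. At its largest possible shares, dilution by free RNA would shift male-biased genes by -0.09 in CDE and -0.48 in TAA, against medians of -2.48 and -5.63. No other source was weighed, and an effect of the exposures on sex-biased expression stays open as a hypothesis, found and tested on the same data.

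Other splits of the same mice were fitted as well. For 3 groups, 4047 genes were called in the real split and at most 1256 in the others. Of 100 splits fitted, out of 280 possible, 1 gave as many, the real one itself. A chance split is thus unlikely to give this count, but 100 splits cannot show a lower share. In hepatocytes the real and highest other counts were 983 and 1 for CDE, 4161 and 0 for TAA and 1442 and 0 for TAA against CDE. For lists they were 14 and 12, 15 and 14, and 19 and 16. Another split thus passed nearly as many lists, so the number of list calls does not set the real groups apart. These comparisons have 10 splits, too few for a share under 0.05. The same holds for endothelial genes (0 and 0 in CDE, 439 and 0 in TAA), stellate genes (0 and 0, 523 and 0) and the 5 endothelial and stellate lists (3 and 4 in CDE, where 4 of 10 splits gave as many; 2 and 3 in TAA, 3 of 10). With 0 calls in CDE, all 10 splits gave as many.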

How the results depend on the processing

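The subtraction of the empty-droplet profile, scaling on the genes tested, calling as first written and values without the low-score cluster were chosen only after the results were seen. No call turned to the opposite direction under any alternative run. Of the values and counts under alternatives, 266 stayed within 1.5 times or on their side of the threshold, 113 moved further, 5 became and 10 ceased to be significant; for lists 1124 stayed, 31 gained and 119 lost their call, and for named genes 5610, 190 and 410. Depth limits the CDE hepatocyte results, as CDE 1 gave 105 hepatocyte nuclei, and the cause of each change below was not tested except where fewer genes, nuclei or mice entered. Thinned to the smallest total, hepatocyte counts were 505 (CDE), 1645 (TAA), 603 (TAA against CDE) and 1629 (3 groups), the stellate TAA count 295, the macrophage CDE count 2 and the cholangiocyte TAA count 173. Without the low-score cluster the hepatocyte counts were 615, 2254, 307 and 2165, detection genes 7, and the exact zonation p 0.0857. DESeq2 gave 1910 for CDE and 2279 for TAA against CDE in hepatocytes, 18, 10, 11 and 5 for CDE in endothelial, stellate, macrophage and cholangiocyte nuclei, and 297 for TAA in cholangiocytes. With the replicate block, hepatocyte counts were 824 (CDE), 3636 (TAA), 1144 (TAA against CDE) and 3423 (3 groups), CDE counts 1 in stellate and 0 in macrophage and cholangiocyte nuclei, and the macrophage TAA count 0. With no genes left out for free RNA, CDE and TAA counts were 2 and 744 in endothelial, 2 and 835 in stellate and 11 and 46 in macrophage nuclei, and 13 for CDE in cholangiocytes. With no low-count filter CDE counts were 15, 2, 28 and 63 in endothelial, stellate, macrophage and cholangiocyte nuclei and the macrophage TAA count 154. With the empty-droplet profile subtracted, TAA counts were 176, 239 and 296 in endothelial, stellate and cholangiocyte nuclei, and CDE counts 5 and 4 in macrophages and cholangiocytes. Scaled on the genes tested, CDE counts were 16, 37 and 63 in endothelial, macrophage and cholangiocyte nuclei and TAA counts 200 and 248 in endothelial and stellate nuclei. Calling as first written gave 122 macrophage genes in TAA, under 1% mitochondrial UMIs 5 in CDE, and nuclei of at least 2000 UMIs 225 endothelial genes in TAA and 0 cholangiocyte genes in CDE; macrophages at that depth were not run, with too few nuclei. OrdMag alone called 30247 nuclei. No list call held with an estimated correlation (0, 0, 0 and 0), and fry called 5 (CDE), 10 (TAA against CDE) and 2 (other classes). The covariance of both effects was 0.723 over genes of log2 CPM at least 5. The exact zonation p was 0.0536 with doublets kept and 0.0571 not thinned; the exact p of the injury share was 0.0143 at the 95th percentile, 0.0429 with doublets kept, 0.0429 thinned to 2000 UMIs and 0.0464 not thinned.

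With 1 mouse left out, hepatocyte counts ranged from 348 to 1507 (CDE), 2557 to 4186 (TAA), 313 to 1559 (TAA against CDE) and 2261 to 4201 (3 groups). Other classes ranged from 222 to 502 (endothelial TAA), 0 to 1 (stellate CDE), 361 to 595 (stellate TAA), 0 to 4 (macrophage CDE), 0 to 94 (macrophage TAA), 0 to 3 (cholangiocyte CDE) and 165 to 470 (cholangiocyte TAA), with the lone mouse of a group assumed to vary like the others. Lists ranged from 11 to 17 (CDE), 15 to 17 (TAA), 16 to 19 (TAA against CDE) and 5, without healthy 3, to 12 (other classes), detection genes from 6 to 10, the exact zonation p from 0.00714 without healthy 3 to 0.118 without TAA 1, the exact injury p from 0.0107 without TAA 2 to 0.207 without TAA 1, and the covariance from 0.855 to 1.20.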

Other observations

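The tests of this part were chosen only after the results of the report had been seen. In TAA cholangiocytes 10 of the 12 members of the cell cycle list that were measured, out of 34, rose, with a median log2 fold change of 4.20 against -0.24 for all genes tested (adjusted p = 9.46e-10 by limma camera; adjusted p = 0.282 with an estimated correlation). The rule that leaves out genes that free RNA could supply keeps a gene more readily when it is high in TAA nuclei, so the choice of measured members leans towards a rise. In TAA stellate nuclei it left 3 members, and the list is not read there. In TAA macrophages 1 member was measured and the list did not pass (adjusted p = 0.670). A cholangiocyte cluster of 128 nuclei (60.9% from TAA 3) and a stellate cluster of 74 (52.7% from TAA 3) had Top2a among their top genes. With the empty-droplet profile subtracted the adjusted p in cholangiocytes was 5.89e-07. In CDE no member of the list was called in cholangiocytes (13 measured, median 0.43) or stellate nuclei (11 measured, median 0.03). The p53 target list did not pass in any of these classes, with 1 or 2 members measurable in TAA. Whether the TAA and CDE effects differ in these classes was not tested.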
